A study of Mus musculus with 1000 samples.

How the data were processed

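Whole-brain RNA without the cerebellum was extracted from 1000 mice, and 4 ng of each RNA was converted into 3' cDNA with in-line indices, per the labels' protocols. The same protocols state that each plate row gave a pool of 12 libraries and that 1152 libraries were combined for sequencing. The submitters' processing notes name the aligner GSNAP, without a version, and the mouse genome build GRCm38. How aligned reads were counted or normalized is not given in the sources used here.

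The only table used was deposited by the authors as a lookup list of the whole screen. Per the file headers, each of its 23231 rows holds a running number, a library name and the name of 1 of 3 parts, and it contains no count, normalized expression value or other measurement. The expression values themselves were not analysed here. The comparisons of gene expression that had been planned for the case that the table held values per gene, with their gene lists for interferon response, microglial activation, homeostatic microglia, complement and antigen presentation, reactive astrocytes and other brain cell types, were therefore not made, and the rule for choosing genes to name was not applied. The other 22231 rows carry names that are not among the 1000 samples and were not used.

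Each sample was matched to the table by its whole title. Titles were split into a prefix (the text before the generation mark), a mouse number, a well, a plate number (after "neuro"), an S number and, in some, a trailing run number. Samples were grouped by prefix. The S number together with the plate number was taken as the pool, after it was checked that each such pair occurred with 1 plate row and each plate row with 1 such pair. The meaning of the plate number and S number was inferred from this layout and is not stated in the labels. Mouse number and run number are also names used here for parts of the title.

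Prefixes with at least 2 libraries that lay within 1 pool were counted. A one-sided permutation test of this count, with pool labels permuted over all libraries 100000 times, had been fixed before the data were examined and was run, after the routine was tested on simulated layouts with and without nesting. Its p is not reported as evidence, because random placement over 86 pools gives a count of 0 almost surely. Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 were used. The alternatives, fixed at the same time, were matching without the trailing run number, counting each form of name alone, defining a pool by plate row, and requiring at least 10 libraries per prefix. Because no reads or counts were analysed, no depth, confidence interval or detection limit can be given for any library.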

Results

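The study screened mouse brains by 3' RNA sequencing. Its design text describes a search for animals with abnormal inflammatory states, followed by exome sequencing to find variants that might account for them. Founder males of the inbred strain C57BL/6NCrl had received 3 doses of 100 mg/kg of ENU (N-ethyl-N-nitrosourea), an alkylating agent that induces mainly point mutations in the germ line. Induced mutations were bred to homozygosity, and whole brains without the cerebellum were taken from mice of generation 3, usually at 8 to 12 weeks of age. This part of the screen comprised 1000 libraries. The labels named no control group, treatment or genotype, and all 1000 libraries carried the same tissue label.

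No gene expression value was analysed here, because the table used assigns library names to parts of the data and holds no measurement. Which inflammatory, glial or neuronal genes differed between animals or pedigrees was therefore not examined, and the sequencing depth of each library is unknown. The results below describe only how the animals were distributed over name groups, plates and pools, which sets the comparisons that expression values from these libraries would allow.

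All 1000 library names were found in the table, and all 1000 were assigned to part 3 of its 3 parts. The names fell into 91 groups that shared the text before the generation mark, called name prefixes here. The labels state that several siblings per pedigree were screened, typically 12, but do not state that a prefix is a pedigree. Counting only libraries of this series, the median prefix held 12 libraries, and the mean was 10.989 ± 2.593 (SD, n = 91 prefixes). Of the 91 prefixes, 76 held exactly 12 libraries, 2 held 11, 1 held 9, 9 held 6 and 3 held a single library. The prefix of 9, ENU56330B6, came first in name order among names without a run number. ENU56378B6, with a single library, came last among names with a run number. Their counts, and so the mean, may be low because the series stops there in name order, which was not checked. Within a prefix, no mouse number was used more than once (0 repeats among 1000 libraries), so the names gave each library its own animal. Mouse numbers ran from 1 to 29.

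The libraries lay on 20 plates, taken as the number that follows "neuro" in each name, with 24 to 84 libraries of this series per plate. No pair of libraries occupied the same well (0 pairs). The protocol joined the 12 cDNAs of a plate row into one pool before the sequencing adapters were added, so that all later steps acted on whole pools. The 1000 libraries came from 86 such pools. Of these, 81 pools held 12 libraries, 3 held 6, 1 held 9 and 1 held a single library of this series.

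The next comparison asked whether name prefixes and pools were crossed or nested. Within this series, all 88 prefixes with at least 2 libraries lay within a single pool. Here 0 prefixes extended over more than 1 pool or more than 1 plate. The other 22231 rows of the lookup list were not searched for these prefixes, so some may extend beyond this series. In 81 of the 86 pools, the libraries of this series all shared 1 prefix. For these 81 prefixes the prefix and the pool cannot be told apart by a comparison between prefixes within this series. Libraries that shared a prefix also shared their pool and plate, so a comparison among them would involve neither difference. The other 5 pools each held libraries of 2 prefixes.

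Those 5 pools covered 10 prefixes. In 3 of them, prefixes of 6 libraries each shared the row, namely ENU56226B6 with ENU56285B6, ENU56090B6 with ENU56260B6, and ENU56108B6 with ENU56290B6. These are the pools in which 6 animals of one prefix could be compared with 6 of another within the same library preparation, counting only libraries of this series. In the remaining 2 pools, 11 libraries of ENU572B6 shared the row with 1 library of ENU57002B6, and 11 libraries of ENU576B6 shared it with 1 library of ENU57006B6.

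The names came in 2 forms, with or without a trailing number, called the run number here. The form without it covered 471 libraries of 42 prefixes on 9 plates. The form with it covered 529 libraries of 49 prefixes on 11 plates, all numbered higher than those 9. No plate and no prefix contained both forms (0 of 91 prefixes). A comparison between prefixes of the 2 forms would therefore also be a comparison between the 2 sets of plates.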

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

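The 7 alternative values say little about stability, because most could not differ from the reported ones. Matching without the trailing run number again found 1000 names, all of which had already matched exactly, and the median prefix held 12 libraries in either form of name alone. Defining a pool by plate row left 88 of 88 prefixes within 1 pool, and requiring at least 10 libraries left 78 of 78. Both follow by construction, since rows and S numbers corresponded one to one and the 78 are a subset of the 88. Joining the 2 lone libraries to the prefix of 11 in their pool, an alternative chosen after seeing the data, gave 89 prefixes, a median of 12 and again 88 of 88 within 1 pool, which joining libraries of one pool cannot change. No paired analysis was possible because the mouse number names a different animal in each prefix and no measured value was compared. The alternatives fixed for gene expression (normalization, low-value filter, plate term and outlying libraries) were not run, and leaving out replicates does not apply, because no expression values were analysed here. The absence of expression values limits every statement to the layout.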

Other observations

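Both tests in this part were chosen after the layout had been seen.

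The 2 pools with 11 libraries of one prefix and 1 of another have a common form. ENU57002B6 and ENU57006B6 each contributed a single library, mouse number 1 in column 1. The rest of the row held ENU572B6 or ENU576B6, whose lowest mouse number was 2 and whose lowest column was 2. Among the 76 prefixes of 12 libraries, 12 (15.8%) lacked mouse number 1, as both prefixes of 11 do. A candidate explanation is 1 family written under 2 spellings, with and without padding zeros; on that reading the 1000 libraries form 89 prefixes and only 3 pools hold more than 1. The numbering that prompted this hypothesis is not a test of it. The share of 15.8% lies under the limit of 25% first set for calling such a lack rare and over the limit of 5% that replaced it after the share had been seen, so the outcome depends on that choice. Both pools lie on 1 plate, and the next row of that plate holds ENU5753B6, a prefix of 12 libraries that is also a short name. Names such as ENU57018B6 and ENU57049B6, on other plates, have the longer form. Short names on this plate were thus not limited to the prefixes of 11. That goes both with the hypothesis and with separate families, so it cannot decide between them. It does not show that a short and a long name stand for 1 family. The hypothesis is left open, and separate families placed side by side remain possible. If the hypothesis held, grouping by name as written would split 1 animal from each of the 2 families.

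Across all 1000 libraries, 18 of the 68 S numbers occurred on 2 plates, but 0 did so within either form of name. A candidate explanation is 2 sequencing batches of 12 plates each, numbered afresh. With plates counted from 0 at the lowest plate number of each form and rows from 1, the S number equalled 8 times the place of the plate plus the place of the row in 86 of 86 pools. On this hypothesis each prefix would lie in 1 batch as well as 1 pool, so a batch effect on expression could be examined only between prefixes. No biological explanation was tested, since no group in the labels bears on how libraries were numbered.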
